A study of Mus musculus with 12 samples.

How the data were processed

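Total RNA of the apical part of the first mandibular molar germ at postnatal day 4 was sequenced from 6 Nfic-null and 6 heterozygous littermate mice, per the labels. Per the submitters' processing notes, reads were aligned with TopHat2 to mm10. The version of the aligner, the counting tool and the annotation are not given in the sources used here. The deposited table holds 25899 genes in 12 libraries and is described as RPKM. Its values run from -11.1 to 16.7, so they were read as log2 of RPKM, as deposited by the authors, where a table of linear RPKM had been assumed before the data were examined. Base 2 was settled from the values. Back-transformed and summed over annotated gene length, they came to 0.773 to 0.835 of the reads with base 2 and to an impossible 8.23 to 28.4 times the reads with base e. Genes with no reads carried a floor of 0.9 reads. Of 7082 values under 20 reads in 2677 genes, 100% came out as whole reads within 0.02 reads, and the depth so read was 70.1 to 96.2 M reads per library. One read in a gene of 1 kb then equals about 0.01 RPKM. Identifiers were matched to GENCODE M21 (GRCm38) for 24987 genes and not for 912, and 4897 genes lay at the floor in all 12 libraries.

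Values were turned back to RPKM and analysed as log2(RPKM + 1). Genes with a mean of 1 RPKM or more (12094) were compared between genotypes with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance and genotype as the only term, and p-values were adjusted by Benjamini-Hochberg at 0.05. Counts were not used here, so no count test was made. Nfic was tested by an exact 2-sided permutation of the library labels. Of 42 gene lists, 40 with 3 or more tested members were tested with camera at a preset correlation of 0.01. The lymphoid list and the X-inactivation list had too few tested members. The test, the lists, the threshold and the other settings listed below were chosen before the data were examined. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

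The genes named were Nfic, then the 10 genes of each direction with the smallest p where too few passed the threshold, then Gli1, Ptch1, Hhip, Smo and Shh. For lists that passed, and for the tooth and cell cycle lists in any case, the 4 members with the smallest p were eligible, or 2 for lists of other cell types. Predicted genes and clones were not named under this rule, and some genes that it names are not reported here.

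The series text speaks of 6 pairs of littermates, and the numbers 5 to 10 occur once in each genotype, so equal numbers were read as pairs, although no label states it outright. The deviations of same-numbered libraries from their group means correlated at r = 0.492, 0.00502, 0.310, 0.667, 0.688 and 0.802 for numbers 5 to 10, and for 3 of 6 numbers the partner was the closest library of the other genotype. These were numbers 8, 9 and 10. Libraries 8 and 9 of both genotypes also shared intestinal transcripts, as described below, so their r does not speak for the pairing alone. Same-numbered libraries had the same pattern of sex-linked genes in 6 of 6 numbers. Numbers that repeat in the column names show at least 2 sample sheets. Libraries 5 to 7 and 8 to 10 were read here as separate sequencing runs, each with 3 libraries of each genotype, although no label names a run.

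The procedure was tested on simulated data with the spread of the 12094 genes, in 20 draws with 200 changed genes. It called 46.3%, 90.2% and 98.7% of genes changed by 0.5, 1 and 2 log2, and 1.73% of calls were false. These shares hold for that number and mix of changes, since fewer or smaller changes make the adjustment stricter. A list of 25 genes shifted by 0.5 was called in 20 of 20 draws and of 40 unshifted random lists in each draw 2 were called over the 20 draws. Those lists were drawn at random from all tested genes. The 40 fixed lists gave more calls under regrouped libraries, a median of 13 over random splits and of 12 over swaps of genotype within pairs. The real grouping was left out of these medians, but some of the other groupings still part the genotypes unevenly. The other settings were the pair as a block, other pseudocounts, filters and scalings, variance without trend or with a robust fit, library weights, a Y-linked covariate, each library or pair left out, a rank test, and other list tests. Alternatives with the run, with tissue makeup as a covariate, without libraries 8 and 9 and without both libraries numbered 6 were added after the values had been seen.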

Results

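Messenger RNA was measured by RNA sequencing in the apical, root-forming part of the first mandibular molar germ of C57BL/6 mice at postnatal day 4. The 12 libraries fell into 2 groups of 6, mice lacking both copies of Nfic (null) and littermates with 1 functional copy (heterozygous controls). Nfic encodes a member of the nuclear factor I transcription factors that is required for molar root formation. The series title places the comparison in a cascade from Nfic to Hedgehog signalling in root development. The libraries carry the numbers 5 to 10 in each genotype, which were taken to mark the 6 littermate pairs that the series describes. The values behind each library corresponded to 70.1 to 96.2 M reads, and 11014 to 12518 genes had 1 RPKM or more. Amelx, which encodes the main enamel matrix protein amelogenin, alone took 3.40% to 13.5% of the gene reads.

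Nfic transcript was lower in the null molars in 6 of 6 pairs but was not absent. Nfic (ENSMUSG00000055053, chromosome 10, 81396186 to 81455635, minus strand, GRCm38) had 16.8 ± 4.42 RPKM in the heterozygous controls and 11.4 ± 3.02 RPKM in the null molars (SD, n = 6 each). The difference was -0.52 on the log2(RPKM + 1) scale (SE 0.178), or 69.7% of the heterozygous level of RPKM + 1. The exact 2-sided permutation test over 924 assignments gave p = 0.0303, and the exact sign-flip test over the 6 pairs gave p = 0.0312, the smallest it can give. The control carried 1 intact copy. Values of single exons were not used here, and where the remaining signal in the null molars came from was not tested. The permutation p was above 0.05 without heterozygous replicate 6 (p = 0.0519), heterozygous replicate 10 (p = 0.0628), null replicate 5 (p = 0.0541) or null replicate 6 (p = 0.0541). The difference was -0.57 in libraries 5 to 7 and -0.47 in libraries 8 to 10, which were read as separate sequencing runs (exact permutation p = 0.2 in each, where 3 against 3 cannot go below 0.1). Across all genes limma gave Nfic an adjusted p of 0.934.

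Hedgehog pathway genes did not move as a block in the null molars. The ligand Shh (chromosome 5, 28456815 to 28467256) had 117 ± 59.6 RPKM in heterozygous and 148 ± 25.3 RPKM in null molars (SD, n = 6 each), higher in 5 of 6 pairs. The pathway effector and target Gli1 (chromosome 10, 127329882 to 127341974) had 17.1 ± 5.30 and 21.7 ± 3.18 RPKM, also higher in 5 of 6 pairs, a difference of 0.36 (SE 0.168) in log2(RPKM + 1). The receptor gene Ptch1 differed by -0.06 (SE 0.165), and the transducer Smo differed by -0.06 (SE 0.116). Hhip, which encodes a secreted Hedgehog antagonist and is itself a target, stood lower at 2.83 ± 1.23 against 5.05 ± 2.40 RPKM, and so did the forkhead genes Foxf2 (7.78 ± 3.50 against 14.5 ± 6.37 RPKM) and Foxf1a (16.9 ± 6.77 against 26.6 ± 9.02 RPKM), each in 5 of 6 pairs. None of these genes passed the threshold over all genes. Their adjusted p by limma with Benjamini-Hochberg adjustment was 0.934 for Gli1, Hhip, Foxf2 and Foxf1a, 0.965 for Shh and 1 for Ptch1 and Smo. Without null replicate 6 the differences of Hhip, Foxf2 and Foxf1a were -0.43, -0.55 and -0.42, against -0.66, -0.86 and -0.69 with all libraries, and without heterozygous replicate 6 that of Shh was 0.66 against 0.44. The signs of Ptch1 and Smo turned positive without the libraries numbered 6, to 0.11 and 0.04.

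**Figure D1:**
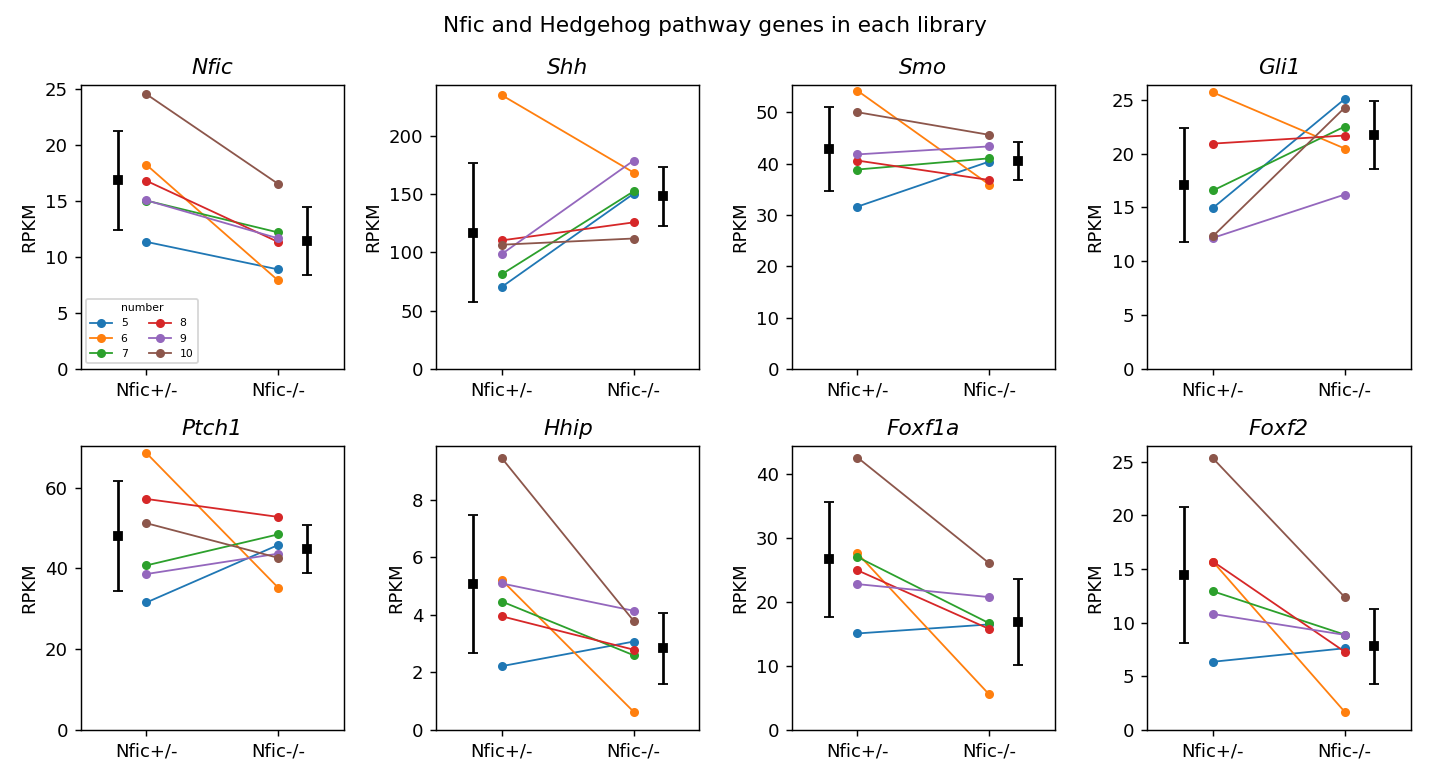
RPKM of Nfic and 7 Hedgehog pathway genes (vertical axis, linear from 0) in each library, with a line joining the heterozygous and null libraries of the same number and a black square with a bar for the mean ± SD of 6 libraries. Nfic falls along 6 of 6 lines to a null mean of 11.4 RPKM, whereas the null library lies higher for Gli1 and Shh on 5 of 6 lines and lower for Hhip and Foxf2 on 5 of 6.

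As groups, the list of 14 Hedgehog targets was lower in the null molars by a mean of -0.30 log2 (limma camera with a preset correlation of 0.01, adjusted p = 0.00107), and the list of 19 pathway components was not shifted (mean -0.04, adjusted p = 0.905). Of the targets, 2 stood above 0 and 0 of 14 passed when adjusted over the list alone. The target list was -0.35 in libraries 5 to 7 and -0.25 in libraries 8 to 10, and its mean level was lower in 4 of 6 pairs. Under an estimated correlation its adjusted p = 0.598, and without null replicate 6 its mean was -0.17. Among the 3 measured nuclear factor I genes, Nfic was the only one that passed when adjusted over the list alone, and the list as a whole did not pass (adjusted p = 0.182).

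Over the whole transcriptome, no single gene separated the genotypes past the threshold. The keratin genes Krt14 and Krt16 were among the genes with the smallest p in the higher direction, and the collagen cross-linking gene Lox was among those in the lower direction. Of 12094 genes tested with limma, 0 passed an adjusted p of 0.05, in either direction, and the smallest adjusted p was 0.934. An unadjusted p under 0.05 was found for 646 genes, 317 higher and 329 lower, where 604.7 were expected by chance. With the littermate pair as a block the count was again 0, with 981 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0872, and an exact rank test also gave 0, with 461. The median SE over genes was 0.113. Simulated libraries with the spread of these 12094 genes had 200 genes changed by 0.5, 1 or 2 log2. There the same test called 46.3% of genes changed by 0.5 log2 and 90.2% of genes changed by 1 log2. With fewer or smaller changes the adjustment is stricter, so these shares do not tell how many such changes would be found here.

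The 10 genes with the smallest p in the higher direction were Fhl2, Krt16, Ckmt1, Myo19, Klk8, Fxyd4, Krt14, Fxyd3, Angptl7 and Cdc42se1. All 10 stood higher in 6 of 6 pairs. Krt14, the basal epithelial keratin, had 507 ± 77.3 RPKM in heterozygous and 691 ± 75.6 RPKM in null molars (SD, n = 6 each; chromosome 11, 100203162 to 100207548), a difference of 0.45 (SE 0.114). Krt16, a keratin of stratified epithelium, had 8.25 ± 1.07 and 11.5 ± 1.33 RPKM, Fhl2, which encodes a LIM-domain cofactor, had 15.5 ± 1.46 and 20.9 ± 1.56 RPKM, and the serine protease gene Klk8 had 8.99 ± 2.08 and 13.1 ± 1.29 RPKM. Fxyd4 and Fxyd3, which encode regulators of the sodium pump, differed by 0.61 (SE 0.153) and 0.52 (SE 0.131). In the lower direction the 10 genes were Lox, Creb3l1, Fhod3, Rassf4, Sdc3, Trps1, Sntb1, Serpinf1, Pmp22 and Leprel1 (P3h2 in the annotation). Lox, which encodes the collagen cross-linking lysyl oxidase, had 35.3 ± 4.46 and 23.2 ± 5.69 RPKM, a difference of -0.61 (SE 0.143) with 6 of 6 pairs lower. Sdc3, a heparan sulphate proteoglycan gene, had 35.9 ± 6.61 and 21.8 ± 6.89 RPKM, and Serpinf1, whose product acts in bone mineralization, had 254 ± 24.4 and 185 ± 35.0 RPKM. Creb3l1, a transcription factor gene of collagen secretion, differed by -0.55 (SE 0.132). Unadjusted p-values of the 20 genes ran from 9.15e-05 (Fhl2) to 0.00256 (Leprel1), and each had an adjusted p of 0.934. Within single sequencing runs the differences lay from 0.23 to 0.73 for the genes higher and from -1.07 to -0.20 for those lower, which is no independent check, since the 20 genes were picked from the same libraries.

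**Figure D2:**
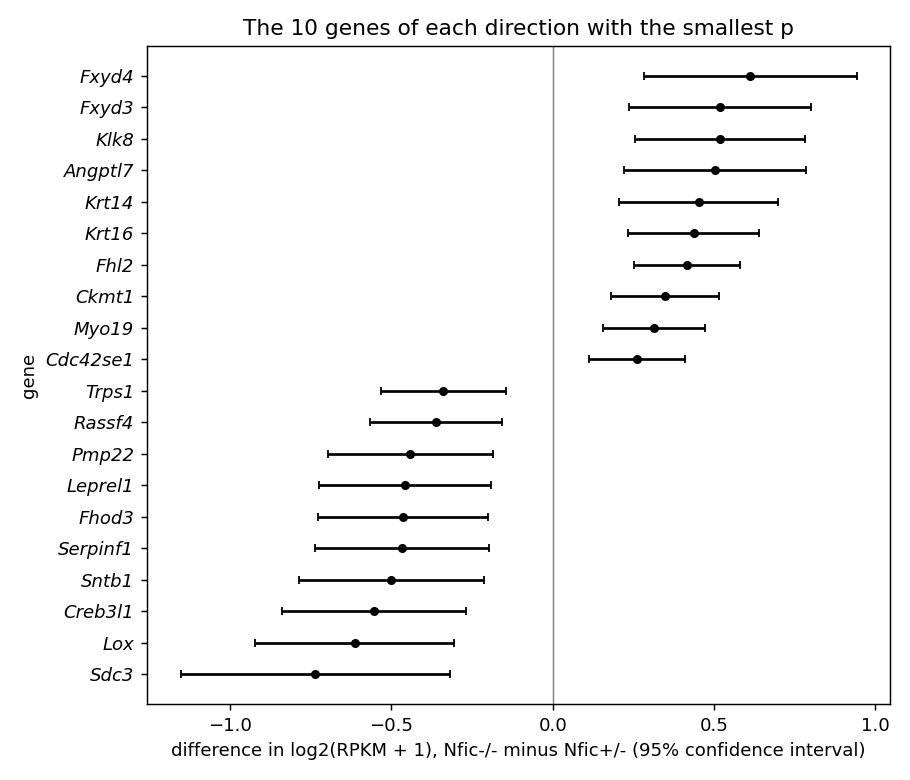
Difference between null and heterozygous molars in log2(RPKM + 1) (horizontal axis) for the 10 genes of each direction with the smallest unadjusted p, with the 95% confidence interval of each from limma, 6 libraries per group. Intervals exclude 0 before adjustment, from Fxyd4 at 0.61 to Sdc3 at -0.74, and each gene had an adjusted p of 0.934.

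Lists of the mineralizing and connective tissue of the molar were lower in the null molars. Of 28 tested odontoblast and dentin genes 25 stood below 0, with a mean of -0.31 log2 (camera adjusted p = 3.58e-08) and a lower level in 5 of 6 pairs. Dspp, the gene of the main dentin phosphoproteins, had 614 ± 129 RPKM in heterozygous and 445 ± 135 RPKM in null molars (SD, n = 6 each), lower in 5 of 6 pairs, the mineralization gene Phex had 39.0 ± 9.71 and 25.6 ± 9.04 RPKM, and the matrix protein gene Sparc had 928 ± 145 and 697 ± 178 RPKM. The list was -0.42 in libraries 5 to 7 and -0.20 in libraries 8 to 10. The dental mesenchyme list of 19 transcription factor and signalling genes had a mean of -0.35 (adjusted p = 9.42e-05), with Msx1 at 38.2 ± 10.2 and 24.5 ± 15.5 RPKM and Pax9 at 1.81 ± 0.845 and 0.996 ± 0.594 RPKM, each lower in 6 of 6 pairs, and Barx1 lower in 5 of 6. The 21 dental follicle and ligament genes had a mean of -0.44 (adjusted p = 1.12e-06). Fmod, a collagen-binding proteoglycan gene, had 39.4 ± 19.98 and 20.1 ± 24.4 RPKM, Bgn, another, had 128 ± 22.1 and 85.1 ± 21.6 RPKM, and Postn, a ligament matrix gene, had 23.5 ± 7.13 and 14.3 ± 10.1 RPKM, each lower in 6 of 6 pairs. The level of the mesenchyme list and of the follicle list was lower in 4 of 6 pairs. The means of these 2 lists were -0.49 and -0.52 in libraries 5 to 7 and -0.22 and -0.36 in libraries 8 to 10. By camera with an estimated correlation the adjusted p was 0.471 for the odontoblast list and 0.598 for the other 2, so no call held. Without null replicate 6 the mean was -0.21 for the mesenchyme list and -0.26 for the follicle list, and without both libraries numbered 6 these were -0.14 and -0.22.

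Collagen, matrix protease, bone and cartilage lists were also lower. The 33 collagen, elastic fibre and collagen-modifying genes had a mean of -0.40 (adjusted p = 3.85e-08) and a lower level in 5 of 6 pairs, and Lox was the 1 member that passed when adjusted over the list alone. Its members did not all go the same way, since the lysyl hydroxylase gene Plod2 stood at 151 ± 33.4 RPKM in heterozygous and 194 ± 20.4 RPKM in null molars (SD, n = 6 each). The 19 matrix protease and inhibitor genes had a mean of -0.26 (adjusted p = 3.37e-05), with the procollagen protease gene Adamts2 at 13.0 ± 1.79 and 9.01 ± 1.95 RPKM and the urokinase receptor gene Plaur higher at 8.01 ± 2.05 and 11.02 ± 2.23 RPKM. The bone list of 15 genes had a mean of -0.20 (adjusted p = 0.0281). The cartilage list of 6 genes had a mean of -0.50 (adjusted p = 0.0407) and was lower in 6 of 6 pairs, although its members diverged. Col9a2 had 48.8 ± 34.9 and 20.9 ± 25.2 RPKM and was lower in 6 of 6 pairs, and Col9a3, which encodes another chain of the same collagen, had 62.1 ± 19.2 and 89.0 ± 14.5 RPKM and was the 1 member that passed, upward, when adjusted over the list alone. In libraries 5 to 7 and 8 to 10 the means were -0.44 and -0.35 for collagens, -0.29 and -0.22 for proteases, -0.27 and -0.13 for bone, and -0.66 and -0.34 for cartilage. With an estimated correlation each of these 4 lists had an adjusted p of 0.598. Without null replicate 6 the mean was -0.24 for collagens, -0.11 for proteases and -0.09 for bone, while the bone call was lost without heterozygous replicate 5 (adjusted p = 0.117), heterozygous replicate 8 (0.113) or null replicate 10 (0.156), and the cartilage call was lost without any of heterozygous replicates 5, 7 and 9 or null replicates 6, 7 and 9 (adjusted p from 0.0548 to 0.137).

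Epithelial lists were higher in the null molars in every pair, but the dental epithelium list by only 0.0201 in pair 6 and 0.0193 in pair 10. In the other pairs that list was higher by 0.14 to 0.70. The dental epithelium list had 30 of 31 members above 0, a mean of 0.27 log2 (camera adjusted p = 6.25e-14) and a higher level in 6 of 6 pairs, and 1 member, Krt14, passed when adjusted over the list alone. Krt17, another basal keratin gene, had 410 ± 52.6 RPKM in heterozygous and 549 ± 105 RPKM in null molars (SD, n = 6 each), and the hemidesmosomal collagen gene Col17a1 had 90.9 ± 7.82 and 110 ± 9.48 RPKM, both higher in 6 of 6 pairs. All 12 members of the oral keratinocyte list, which holds stratified and cornifying epithelium genes, stood above 0, with a mean of 0.33 (adjusted p = 3.31e-06), a higher level in 6 of 6 pairs and Krt16 as the 1 gene past the threshold over the list alone. The 2 lists had means of 0.38 and 0.51 in libraries 5 to 7 and 0.15 and 0.16 in libraries 8 to 10. Under an estimated correlation their adjusted p was 0.471 and 0.514, and the keratinocyte mean dropped to 0.13 without null replicate 7. The enamel list of 11 genes did not pass with all 12 libraries (mean 0.002, median 0.18, camera adjusted p = 0.59), with 8 members above 0 and 3 below. It includes Dspp (-0.49), which is also in the odontoblast and dentin list, so it is not a list of enamel genes alone. The difference of the enamel list ran from -0.88 in pair 5 to 1.23 in pair 6. Without pair 6, under the block, it was lower (mean -0.24, camera adjusted p = 0.00474), whereas without pair 5 or pair 9 it was higher (means 0.18 and 0.12, adjusted p = 0.0193 and 0.046), and without heterozygous replicate 5 alone it was 0.19 (adjusted p = 0.0069). These calls rest on the preset correlation, and with an estimated one the enamel list had an adjusted p of 0.905 over all libraries and 0.893 under the block. Enam, an enamel matrix gene, had 1442 ± 371 and 1714 ± 257 RPKM, and the enamel protease gene Klk4 had 6.36 ± 5.16 and 2.78 ± 0.431 RPKM. The Enam difference was 0.28, or 0.15 without heterozygous replicate 6, and that of Klk4 was -0.66, or -0.43 and -0.41 without heterozygous replicates 5 and 7.

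Cell cycle genes were lower by small amounts. The 28 genes of the G1 and S phases had a mean of -0.17 (adjusted p = 0.00019) and 0 of the 29 genes of G2 and mitosis stood above 0, with a mean of -0.22 (adjusted p = 8.33e-06). The replication licensing gene Mcm6 had 8.11 ± 4.11 RPKM in heterozygous and 5.75 ± 2.41 RPKM in null molars (SD, n = 6 each), and Top2a, the DNA topoisomerase gene of dividing cells, had 5.34 ± 2.67 and 3.93 ± 1.42 RPKM. Both list levels were lower in 4 of 6 pairs, at -0.27 and -0.32 in libraries 5 to 7 and -0.06 and -0.11 in libraries 8 to 10. By camera with an estimated correlation the adjusted p was 0.674 for each. Mcm6 differed by -0.39, or -0.19 without heterozygous replicate 10, and Top2a by -0.32, or -0.14 without heterozygous replicate 10 and -0.21 without null replicate 6. The G1 and S mean lay at -0.07 without heterozygous replicate 10, -0.10 without null replicate 6 and -0.26 without heterozygous replicate 5. The mean of the G2 list lay at -0.13 without heterozygous replicate 6, -0.09 without heterozygous replicate 10, -0.14 without null replicate 6 and -0.34 without heterozygous replicate 5. The list of CDK inhibitors and p53 targets did not pass (mean 0.02, adjusted p = 0.178).

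Of the other signalling lists, Wnt targets and inhibitors were lower (22 genes, mean -0.23, adjusted p = 0.0208) and so were FGF pathway genes (13 genes, mean -0.14, adjusted p = 0.035). Among the Wnt inhibitor genes, Frzb had 6.89 ± 3.17 RPKM in heterozygous and 3.68 ± 1.74 RPKM in null molars (SD, n = 6 each), Dkk1 had 13.7 ± 3.58 and 9.42 ± 3.25 RPKM, and Apcdd1 went the other way, at 45.9 ± 4.83 and 57.2 ± 10.4 RPKM. The FGF receptor gene Fgfr3 had 6.11 ± 3.05 and 3.97 ± 3.90 RPKM and was lower in 6 of 6 pairs. The Wnt list was -0.30 and the FGF list -0.16 in libraries 5 to 7, and they were -0.16 and -0.12 in libraries 8 to 10. With an estimated correlation the adjusted p was 0.674 for the Wnt list and 0.648 for the FGF list. The Wnt mean was -0.10 without null replicate 6, and its call was lost without heterozygous replicate 8 (adjusted p = 0.0968) or null replicate 10 (0.0988). The FGF mean was -0.09 without heterozygous replicate 10, and its call was lost without any of heterozygous replicates 6 and 8 or null replicates 7, 9 and 10 (adjusted p from 0.0602 to 0.169). Wnt ligands and receptors, BMP, TGF-beta and Notch genes did not pass (adjusted p = 0.696, 0.169, 0.41 and 0.299). The BMP list passed by camera as lower under the block without pair 6 (adjusted p = 0.0431), although its mean there was 0.00312 against -0.11 with all pairs. With an estimated correlation its camera adjusted p was 0.728 over all libraries and 0.717 under the block.

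Markers of cells that lie within the connective tissue were lower together with the mesenchymal lists. All 19 endothelial genes stood below 0, with a mean of -0.38 (camera adjusted p = 2.05e-11), and the vascular receptor gene Kdr had 3.50 ± 0.897 RPKM in heterozygous and 2.33 ± 0.946 RPKM in null molars (SD, n = 6 each). The 10 pericyte and smooth muscle genes had a mean of -0.39 (adjusted p = 0.00105), with the pericyte channel gene Kcnj8 at 16.04 ± 9.05 and 8.46 ± 7.93 RPKM and the pericyte regulator Rgs5 at 21.5 ± 5.48 and 12.7 ± 5.33 RPKM, each lower in 6 of 6 pairs. All 16 macrophage genes stood below 0 (mean -0.36, adjusted p = 3.37e-05), among them the mannose receptor gene Mrc1 at 4.82 ± 2.27 and 3.06 ± 2.78 RPKM. The 9 Schwann cell and nerve genes had a mean of -0.20 (adjusted p = 0.0283), and Pmp22, a myelin protein gene, was the 1 member that passed when adjusted over the list alone. In libraries 5 to 7 and 8 to 10 the means were -0.29 and -0.46 for endothelium, -0.40 and -0.39 for pericytes, -0.56 and -0.15 for macrophages and -0.21 and -0.19 for Schwann cells. Under an estimated correlation the adjusted p was 0.598 for each of the 4. Without null replicate 6 their means were -0.24, -0.23, -0.16 and -0.11, and the Schwann call was lost without heterozygous replicate 8 (adjusted p = 0.109), null replicate 9 (0.0576) or null replicate 10 (0.0956). The level of the endothelial and Schwann lists was lower in 4 of 6 pairs, that of pericytes in 5 and that of macrophages in 3.

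A neuron list with 3 measured genes was higher (mean 0.41, adjusted p = 0.000924), in 5 of 6 pairs, with Stmn2, a gene of growing axons, at 4.34 ± 1.80 RPKM in heterozygous and 6.69 ± 1.79 RPKM in null molars (SD, n = 6 each). It was 0.28 in libraries 5 to 7 and 0.53 in libraries 8 to 10, and its adjusted p = 0.471 with an estimated correlation. Lists of osteoclast, neutrophil, erythroid, skeletal muscle and fat cell genes did not pass (adjusted p = 0.098, 0.905, 0.99, 0.193 and 0.546). The osteoclast list passed as lower without heterozygous replicate 10 (mean -0.19, adjusted p = 0.039), null replicate 5 (-0.28, adjusted p = 0.0339) or null replicate 9 (-0.34, adjusted p = 0.0425). Its mean was -0.23 with all libraries and -0.07 without null replicate 6, and its camera adjusted p with an estimated correlation was 0.674. The skeletal muscle list (mean 0.32) passed as higher under the block without pair 5 (0.37, adjusted p = 0.0332) or pair 8 (0.52, adjusted p = 0.0104), and its mean was -0.09 without null replicate 9. With an estimated correlation its camera adjusted p was 0.676 over all libraries and 0.655 under the block.

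Mitochondrial respiration genes stood slightly higher, with 29 of 30 members above 0, a mean of 0.09 (camera adjusted p = 1.73e-07) and a higher level in 4 of 6 pairs. Uqcrq, a subunit gene of respiratory complex III, had 28.9 ± 1.09 RPKM in heterozygous and 33.4 ± 1.76 RPKM in null molars (SD, n = 6 each), higher in 6 of 6 pairs. Ribosomal protein genes (mean 0.06, adjusted p = 0.0283) and cholesterol synthesis genes (mean 0.06, adjusted p = 0.021) also passed. The respiration list was 0.07 in libraries 5 to 7 and 0.11 in libraries 8 to 10, while the ribosomal and cholesterol lists were -0.05 and -0.03 in libraries 5 to 7 and both 0.16 in libraries 8 to 10. By camera with an estimated correlation the adjusted p was 0.598, 0.784 and 0.721 for respiration, ribosomal and cholesterol genes. The ribosomal call was lost without any of heterozygous replicates 5, 7, 9 and 10 or null replicates 8, 9 and 10 (adjusted p from 0.0554 to 0.177), and the cholesterol call without heterozygous replicate 8 (0.232) or null replicate 8 (0.397). The ribosomal mean ranged from -0.0004 to 0.14 and the cholesterol mean from 0.03 to 0.12 with each library left out in turn. Lists of immediate early, heat shock and unfolded protein, glycolysis and hypoxia, interferon and Y-linked genes did not pass (adjusted p = 0.59, 0.398, 0.135, 0.116 and 0.897). The glycolysis and hypoxia list passed as higher without heterozygous replicate 7 (mean 0.0496, adjusted p = 0.0104) or null replicate 10 (0.0375, adjusted p = 0.0496), and the interferon list as lower without null replicate 10 (-0.29, adjusted p = 0.0453). Under the block the former also passed without pair 7 or pair 10, and the latter without pair 10. With an estimated correlation the camera adjusted p over all libraries was 0.721 for glycolysis and hypoxia and 0.674 for interferon. The interferon mean was -0.18 with all libraries and -0.0928 without null replicate 6.

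**Figure D3:**
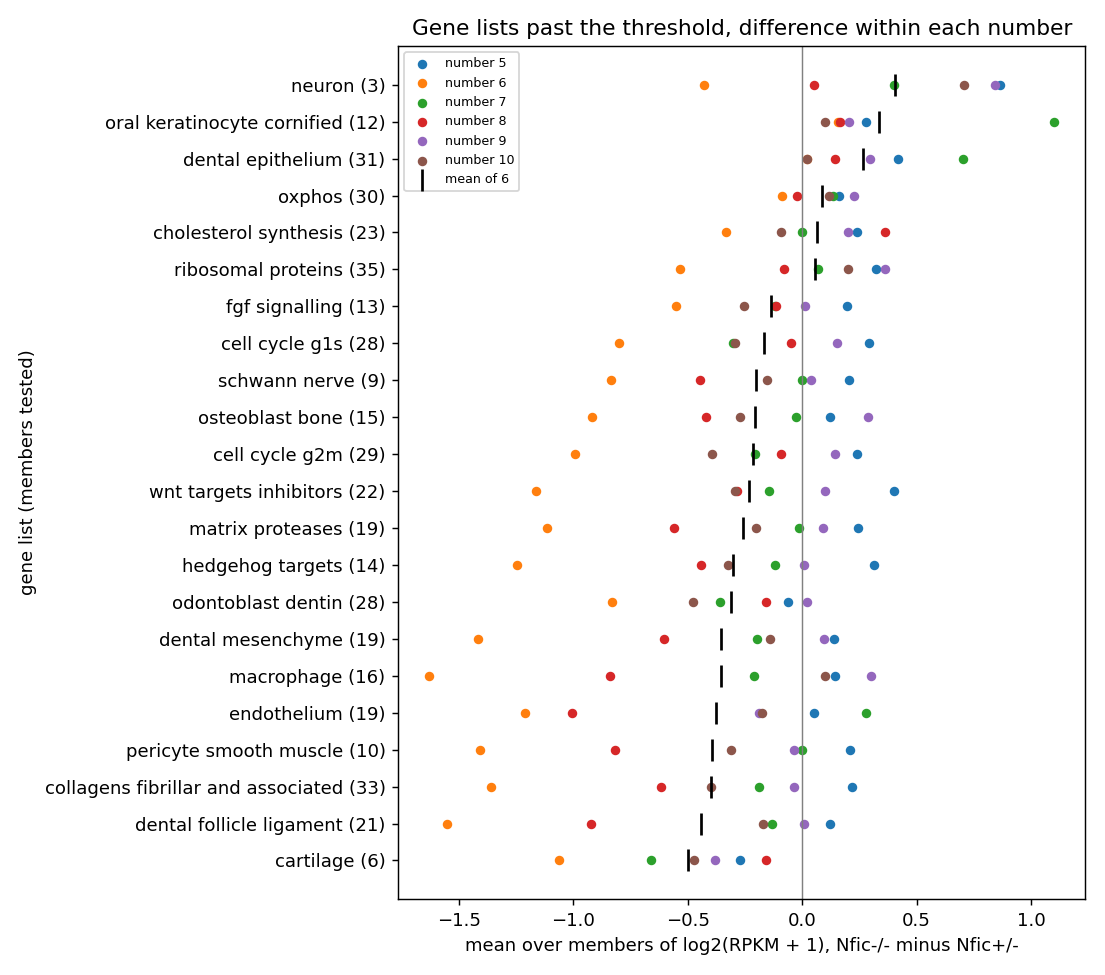
Difference between null and heterozygous molars within each of the 6 pairs (coloured points) and its mean (black bar) for the 22 gene lists past the camera threshold. The horizontal axis is the mean over list members of the difference in log2(RPKM + 1). Pair 6 lies lowest in 20 of the 22 lists, at -1.42 for dental mesenchyme, and the dental epithelium and oral keratinocyte lists lie above 0 in 6 of 6 pairs. The dental epithelium list lies at only 0.0201 in pair 6 and 0.0193 in pair 10.

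In all, 22 of 40 tested lists passed, 6 higher and 16 lower, 0 passed with an estimated correlation (smallest adjusted p = 0.471), and 0 passed an exact permutation of the mean list level between libraries (smallest adjusted p = 0.588). Libraries also differed in ways that genotype did not follow. The first principal component, 44.8% of the variance, ran from null replicate 6 (-39.6) to heterozygous replicate 10 (31.3). The highest Amelx values, 106179 RPKM in heterozygous replicate 5 and 102366 RPKM in null replicate 6, lay at its low end, and the lowest, 28240 RPKM in heterozygous replicate 6, at 24.8. Within pair 6 the mesenchyme list differed by -1.42. The second component, 25.6% of the variance, set the libraries numbered 8 and 9 of both genotypes apart from the other 8. These 4 libraries held transcripts of the small intestine that were close to the floor elsewhere. Defa24, an antimicrobial peptide gene of intestinal Paneth cells, had a mean of 96.3 RPKM in the 4 libraries and 0.0305 RPKM in the other 8, and the enterocyte fatty acid carrier gene Fabp2 had 64.6 and 0.0161 RPKM. The 4 libraries were 2 of each genotype. Without them 0 genes passed the threshold and 21 lists did, 19 of them among the 22. On the third component, 9.44% of the variance, the null library lay lower in every pair except pair 6 (-9.71 against -15.4). Whether that component goes with genotype was not tested.

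**Figure D4:**
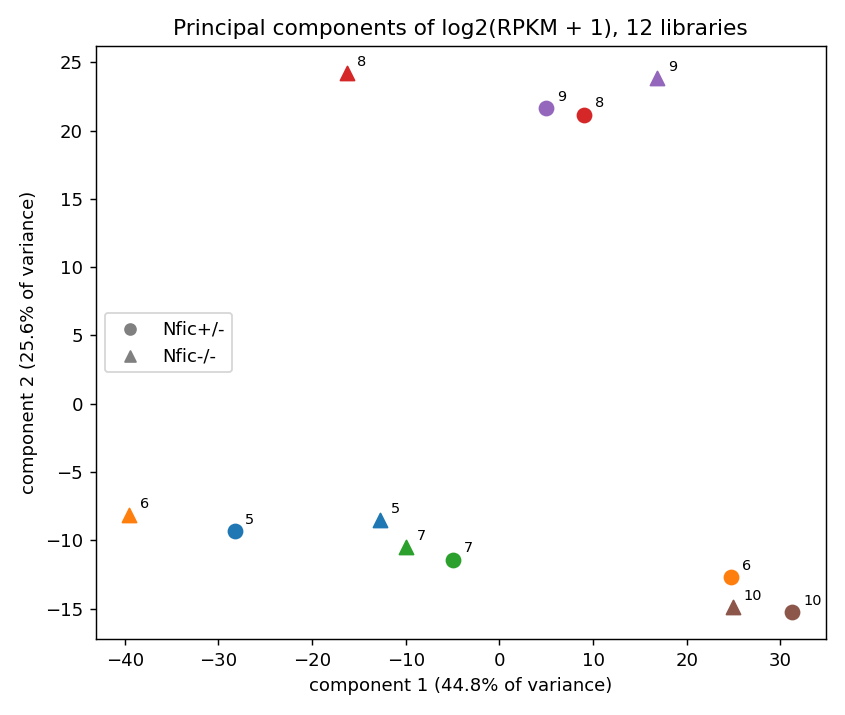
First and second principal components of log2(RPKM + 1) over the 12094 tested genes for the 12 libraries (circles heterozygous, triangles null, coloured and labelled by number). Libraries 8 and 9 of both genotypes lie above 21 on the second component and the other 8 lie below -8.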

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

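Of the tests in this part, those of the sequencing run and of genotype for the intestinal transcripts, those of the mesenchyme, endothelium and epithelium lists, the rescaling test and the test of Gli1 against the mesenchyme list were chosen only after the result was seen. In 16 of 266 groups of 6 libraries the highest or lowest library stood apart from the other 5, by a gap above 0.625 of the group's range. Chance gives this in about 1 in 20 groups, so the number as a whole is close to chance. Values here are log2(RPKM + 1). Null replicate 6 was lowest and apart for Hhip (0.698), Foxf2 (1.42), Foxf1a (2.70), Adamts1 (1.01), Adamts5 (0.509), Ngfr (0.970) and the list of Wnt targets and inhibitors (2.85). Heterozygous replicate 6 was highest and apart for Shh (7.88), Rps27 (3.90) and Dsg1a (3.75). Null replicate 10 was lowest for Col17a1 (6.52), Spry1 (2.16) and the dental epithelium list (4.35). Null replicate 7 was lowest for Uqcrq (4.96) and highest for the oral keratinocyte list (3.56), and null replicate 9 was highest for the skeletal muscle list (3.62).

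Intestinal transcripts were present in the 4 libraries numbered 8 and 9. Over 26 markers not looked at before that reached 0.5 RPKM in any library, the median log2(RPKM + 0.1) difference from the other 8 libraries was 4.55, and 25 of the 26 stood higher in all 4 than in any other library (all 27 without that bound: median 4.47, the same 25, with Dpep1 and Clca1 overlapping), so RNA of intestine from another sample remains a candidate source. The most abundant marker not looked at before was Anpep (21.2 RPKM against 4.26 RPKM elsewhere), and of the markers seen first Defa24 (87.4 to 105 RPKM) and Reg3b (15.0 to 164 RPKM) in the 4 libraries. A sequencing run shared by libraries 8 to 10, as read here, is argued against. Libraries 10 differed from libraries 5 to 7 by a median of -0.0143. Genotype is argued against too, with a median of 0.0336 between null and heterozygous libraries. Both medians partly restate how the pattern was seen, in 4 libraries split evenly between the genotypes, so neither is an independent test. Xist was at 0.199 to 0.424 RPKM in these 4 libraries, which carried Y-linked transcripts, and at most at 0.00505 RPKM in the other libraries with Y-linked transcripts, and how the RNA entered was not tested.

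The mesenchymal, vascular and macrophage lists were lower and the epithelial lists higher in null molars. Enamel transcripts taking more of the reads are argued against, since the mesenchyme list kept 91.9% of its difference after each library was rescaled to 1 median. A smaller share of mesenchymal tissue in the null pieces cannot be told apart from a change within that tissue. Over the 6 pairs the mesenchyme differences went with those of the follicle list (r = 0.984, exact permutation p = 0.00278, adjusted p = 0.00972 over 7 relations; rho = 0.943, exact permutation p = 0.0167; r = 0.935 without the 2 farthest pairs), of macrophages (r = 0.983, exact permutation p = 0.00278, adjusted p = 0.00972; rho = 0.943, exact permutation p = 0.0167; r = 0.784 without the 2 farthest), of pericytes (r = 0.966, exact permutation p = 0.00972, adjusted p = 0.0227; rho = 0.829, exact permutation p = 0.0583; r = 0.616 without the 2 farthest) and, less firmly, of endothelium (r = 0.853, exact permutation p = 0.025, adjusted p = 0.0438; rho = 0.6, exact permutation p = 0.242; r = -0.37 without the 2 farthest), while G2 and mitosis genes (r = 0.880, exact permutation p = 0.0375, adjusted p = 0.0525; rho = 0.771, exact permutation p = 0.103; r = 0.919 without the 2 farthest) and odontoblast genes (r = 0.807, exact permutation p = 0.0556, adjusted p = 0.0648; rho = 0.714, exact permutation p = 0.136; r = 0.911 without the 2 farthest) did not pass. The mesenchyme and epithelium differences had r = 0.511 (exact permutation p = 0.319, adjusted p = 0.319, rho = 0.371, exact permutation p = 0.497, r = -0.127 without the 2 farthest pairs). In a tissue of these 2 parts alone, a changed share needs a negative r. Enamel transcripts are a further large part here (Amelx, 3.40% to 13.5% of gene reads), so this r cannot decide. Over pairs 5 to 10 the enamel list differed by -0.88, 1.23, 0.0161, 0.14, -0.59 and 0.0931. The mesenchyme list differed by 0.14, -1.42, -0.20, -0.61, 0.0942 and -0.14 in the same pairs. That relation was not tested, and an effect of genotype on tissue composition stays open.

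Gli1 stood higher while the mesenchyme list, taken without Gli1, stood lower. The difference of Gli1 relative to that list was 0.755 log2, higher in 6 of 6 pairs (exact permutation p = 0.0281, adjusted p = 0.0758 over 7 Hedgehog genes), and Foxf2 (-0.47, exact permutation p = 0.013) and Foxf1a (-0.29, exact permutation p = 0.0325) went the other way at the same adjusted p, so a share of mesenchyme that Gli1 follows cannot be told apart from a change of Gli1 itself. Gli1 carried by the epithelium also stays open, since over the 6 heterozygous libraries its r with the epithelium list was 0.521 (exact permutation p = 0.268, adjusted p = 0.536 over 2 relations; rho = 0.486, exact permutation p = 0.356; r = 0.421 without the 2 farthest libraries). With the mesenchyme list it was 0.239 (exact permutation p = 0.65, adjusted p = 0.65; rho = 0.314, exact permutation p = 0.564; r = 0.958 without the 2 farthest).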

How the results depend on the processing

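The alternatives with run, libraries 8 and 9 left out, both libraries numbered 6 left out without a block, or a mesenchyme or Amelx covariate were chosen only after the result was seen. The pairing as a block left 0 genes past the limma threshold (981 at an unadjusted p under 0.05). It also left 22 lists and a Nfic difference of -0.52, and it changed no other call. The exact rank test gave 0 genes too, with 461 unadjusted, which its lowest possible p of 0.00216 makes uninformative. Genes passed under 5 of 39 settings. These were library weights (17, 9 higher and 8 lower), the block without pair 6 (11, 2 higher and 9 lower), the block with the mesenchyme covariate (1399, 1277 higher and 122 lower), the same without the libraries numbered 6 (79, 63 higher and 16 lower) and the block with Amelx (209, 124 higher and 85 lower). With each library or pair left out, the count was 0 to 11, with 0 to 2 higher and 0 to 9 lower. The number of lists was 0 with an estimated correlation and 0 with fry, and 17 to 23 otherwise.

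Nfic stayed lower throughout, from -0.63 to -0.41 with 1 library left out, and its exact permutation p was above 0.05 in libraries 5 to 7 alone (-0.57, p = 0.2), in libraries 8 to 10 alone (-0.47, p = 0.2), without libraries 8 and 9 (-0.56, p = 0.143) and without heterozygous replicate 6 (-0.49), heterozygous replicate 10 (-0.41), null replicate 5 (-0.46) or null replicate 6 (-0.43). Without heterozygous replicate 5 or null replicate 10 the exact permutation p was 0.00866 at the same number of libraries.

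With library weights Ptch1 was 0.0624. With libraries or pairs left out Ptch1 ranged from -0.18 to 0.11, Smo from -0.14 to 0.0408 and the enamel list from -0.24 to 0.19. Without both libraries numbered 6 and no block, Ptch1 was 0.11, Smo 0.0408 and the enamel list -0.24. In libraries 5 to 7 alone Rps27 was -0.0272, Rps3 -0.00511, the erythroid list -0.43 and the ribosomal list -0.0457. Without libraries 8 and 9, with the replicate block or not, the erythroid list was -0.31 and the cholesterol list -0.0455. With the mesenchyme covariate Ptch1 was 0.10, Smo 0.0831, Anln 0.0219, Nuf2 0.0253, Ccna2 0.0152, Top2a 0.0308, the enamel list -0.37 and the Y-linked list -0.25. With block and mesenchyme covariate Ptch1 was 0.22, Smo 0.11, Enam -0.0193 and the enamel list -0.42, and without the libraries numbered 6 these were 0.20, 0.11, -0.00456 and -0.43, with Fcer1g at 0.0184 and the cholesterol list at 0.12, where the camera direction turned. With block and Amelx Ptch1 was 0.0812, Smo 0.0233 and the enamel list -0.21. Where the sign of the enamel, erythroid and Y-linked lists is given above for a single setting, they passed the camera threshold as lower, with the enamel list at adjusted p from 8.84e-09 to 0.0167, while the enamel list passed as higher without pair 5 (0.18) or pair 9 (0.12) under the block, and without heterozygous replicate 5 (0.19). The cause was not tested. Among the other values of named genes 3450 stayed on their side of the threshold and 89 gained a call, and among those of lists 1367 stayed, 39 gained a call and 134 lost it. The block with a Y-linked covariate was not run, since both libraries of each pair have the same sex-linked pattern and the block absorbs it.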

Other observations

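Of the tests in this part, the fits with the mesenchyme or Amelx covariate and the fit without the libraries numbered 6 and without a block were chosen only after the result was seen. Leaving out pair 6 under the block, a setting chosen beforehand, 11 genes passed the limma threshold, and they were chosen for naming after their values were seen. Lower in null molars in 5 of 5 pairs were Col9a2, a cartilage collagen gene (-1.29, adjusted p = 0.0157), Crabp1, a retinoic acid binding protein gene (-0.97, adjusted p = 0.0334), Col23a1, a transmembrane collagen gene (-0.85, adjusted p = 0.0314), Rdh10, a gene of retinoic acid synthesis (-0.84, adjusted p = 0.0333), Sall3, a zinc finger transcription factor gene (-0.79, adjusted p = 0.0157), Astn1 (-0.78, adjusted p = 0.0314), Vit (-0.68, adjusted p = 0.0489), Gdf7, a BMP family ligand gene (-0.63, adjusted p = 0.0314), and Nqo1, a quinone reductase gene (-0.63, adjusted p = 0.0193). Higher in 5 of 5 pairs were S100a14, an epithelial calcium-binding protein gene (0.55, adjusted p = 0.0463), and 4933416E03Rik (0.72, adjusted p = 0.0157). Without the block the same 10 libraries gave 0 genes by limma (697 at an unadjusted p under 0.05), with Col9a2 at an adjusted p of 0.881. With pair 6 included 0 genes passed under the block (981 at an unadjusted p under 0.05). The exact rank test on all 12 libraries gave 0, with 461 unadjusted, which its lowest possible p of 0.00216 makes uninformative. Swaps of genotype within the 5 pairs make 16 arrangements, too few for a share under 5%. The real one gave 11 genes and the highest other 0, and 1 of 16 gave as many.

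For the count of 0 genes by limma (646 at an unadjusted p under 0.05; exact rank test 0, with 461 unadjusted and a lowest possible p of 0.00216), 100 of 100 splits of the 12 libraries gave as many, which decides nothing, since no split can give fewer than 0. For the 646 genes 19 of 100 splits gave as many, with a highest other of 6443, and for the 22 lists 8 of 100 did, with a median of 13 and a highest other of 24, so chance cannot be excluded for either. For the 17 genes with library weights 13 of 100 did, with a highest other of 6781. Other splits gave up to 4761 genes past the threshold, which points to a structure of the samples apart from genotype.

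Compared with the 32 swaps of genotype within pairs, which keep every pair parted, the real arrangement gave the most lists under the block, 22 against a median of 12 and a highest other of 20 (1 of 32, the smallest share these swaps can give). The margin was narrow and held only under the block. That share was not adjusted over the other counts tested this way, so chance is not excluded for the count of lists. Among single lists under the block 0 passed with an estimated correlation (smallest camera adjusted p = 0.655), and 0 passed the exact sign-flip test over pairs (smallest adjusted p = 0.417). With 6 pairs the sign-flip p cannot go below 0.0312. Over 40 lists its adjusted p could pass only if most lists reached that floor, so its 0 decides nothing. For the 981 genes at an unadjusted p under 0.05 chance cannot be excluded, since 7 of 32 gave as many, up to 3882. The 1399 genes with block and mesenchyme covariate were matched by 1 of 32, the real one, against a highest other of 89, and the 209 genes with block and Amelx by 1 of 32, against 12. These 2 fits shared 183 genes. Pair 6 gave 66.1% of the spread of the mesenchyme covariate within pairs and 4 residual degrees of freedom were left. Since genotype may itself change the covariate, the 1399 genes are not a measure of its direct effect.

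Near Nfic, 10 of 197 tested genes within 10 Mb had an unadjusted p under 0.05, 5.08% against 5.34% of other genes (Fisher's exact p = 1), which argues against a widespread effect of flanking DNA. Y-linked transcripts were at the floor in 4 libraries, numbers 6 and 10 of both genotypes, with a mean Xist of 10.9 RPKM.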
